A study of Mus musculus with 24 samples.

How the data were processed

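RNA was sequenced from RN2 cells, a mouse acute myeloid leukaemia line that carries the Mll-Af9 fusion and a mutant Nras, before and 4 days after doxycycline was given to switch on a short hairpin RNA. Clones carried 1 of 3 hairpins: shRen713, the control, or shOgdh346 or shOgdh2081, both directed against Ogdh. Each hairpin was represented by 2 clones, and each clone and day by 2 libraries, so that the 24 libraries form 6 groups of 4.

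The deposited values are whole-number counts per Ensembl gene. Per the submitters' processing notes, FastQC 0.11.5, Trimmomatic 0.36, STAR 2.6.1a and featureCounts 1.6.3 were used with the mouse build mm10 (GRCm38); their roles and order are not given in the sources used here. Per the labels' protocols, polyadenylated RNA was made into TruSeq libraries and read as single ends on a HiSeq instrument. The same protocol names a human build, another counting tool and an RPKM matrix. The values checked here do not match that account, since they are whole numbers under mouse gene identifiers. The strand setting, the annotation release and the rule for reads that map to several places are not given in the sources used here. Reads of near-identical gene copies, or of genes that overlap on opposite strands, could therefore have been split or lost, and values of such genes are uncertain. The deposited table also gives a transcript length in bases per gene, which was not used in any test. Coordinates are those of the deposited table.

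The table holds 53465 genes, each with an identifier. Total counts per library ran from 7209186 to 20705468, and between 16876 and 20657 genes had at least 1 count. The 10 most abundant genes took 3.63% to 8.98% of the counts of a library and mitochondrial genes took 1.63% to 2.46%. A count of 0 allows up to 3 counts, which is the floor used for folds against a group with no counts, taken over the group. Intervals and floors cover counting error only. The libraries of a clone and day were compared with a chi-square statistic over genes with at least 20 counts. It came to between 6.78 and 10.3 per gene for the 6 pairs at day 0 and between 1.60 and 2.94 for the 6 pairs at day 4, so that no pair was a repeat of 1 library within counting noise.

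The clone carries the hairpin, so it was taken as the replicate. Counts of the 2 libraries of each clone and day were summed, which gave 12 sums. Genes were filtered with filterByExpr, which left 14249, and scaled with TMM. Changes were tested with edgeR 4.0.16 in R 4.3.3, with robust dispersions and the quasi-likelihood test, in a model with the clone as a block and a day 4 term for each hairpin. This left 3 residual degrees of freedom, to which the fit added a median of 6.11 prior degrees of freedom. That the clones pair the samples comes from the labels. A check of the deviations of clones from their group means gave correlations across genes between day 0 and day 4 of 0.63 to 0.93. Comparisons of hairpins within a day used the same sums in 6 groups, with 6 residual degrees of freedom. Each clone enters this fit at day 0 and at day 4, so its sums are not independent and these degrees of freedom are overstated. All hairpins shared 1 estimate of the spread. With the clone as a block, p-values of changes describe how the day 4 minus day 0 change differs between these clones, 2 per hairpin. Those of comparisons within a day describe the spread of levels between the clones. Standard errors are those implied by the test statistic. Adjusted p is by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Expression levels are CPM on TMM-scaled library sizes, given as the mean and SD over clones.

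The changes tested were the day 4 minus day 0 change of each hairpin, the change of each Ogdh hairpin minus that of the control (the net change), the mean net change of both Ogdh hairpins, and the difference between the Ogdh hairpins. The levels of the Ogdh hairpins were set against the control at day 0 and at day 4. Named genes are Ogdh; for the mean net change, the 12 largest rises and 12 largest falls with adjusted p under 0.05, a mean of at least 5 CPM and the same direction in all 8 comparisons of an Ogdh clone with a control clone; for each other contrast, the 4 largest rises and 4 largest falls with adjusted p under 0.05 and at least 5 CPM; and up to 4 members with the smallest p in each gene list. Predicted gene models and clone names were passed over.

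42 gene lists with 1229 members were fixed in advance, of which 1227 symbols matched the table. They cover central carbon, amino acid, nucleotide and lipid metabolism, enzymes that use 2-oxoglutarate, stress and inflammatory responses, cell cycle, ribosomes, myeloid maturation, leukaemia self-renewal, and markers of other blood and stromal cells. Lists with at least 5 tested genes were tested in limma 3.58.1 with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists of a contrast. The same lists were tested with camera at an estimated correlation and with fry. The correlation was estimated from the 3 residual degrees of freedom of the clone-block fit, so that test could hardly call a list in this design. The samples, comparisons, lists, naming rule and alternatives were fixed before the data were examined, except the alternatives named next.

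Alternatives were 24 single libraries with the clone as a block, 24 libraries with the clone and replicate number as a block, no block, DESeq2 1.42.0, RLE and upper-quartile scaling, no filter, a stricter filter, and each clone and each library left out. Fits with the day 0 libraries of replicate 1 alone or of replicate 2 alone, and a fit of both within-day comparisons with replicate number as a term, were added after seeing the data, as were the counts of genes shared by both Ogdh hairpins under each alternative and a test of Gene Ontology terms. Where a group is left with 1 clone, that clone is assumed to vary like the others.

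The scripts were tested on simulated data drawn from the means and library sizes of these samples, with 200 changed genes among 14249. For the mean net change, 44.3% of genes changed 1.5-fold, 92.9% of genes changed 2-fold and 100% of genes changed 4-fold were recovered, with 10.9% false calls among 175. For the comparison at day 4, the shares were 22.9%, 65.7% and 96.7%, with 2.44% false calls among 123. Contrasts simulated with no effect gave 1 call for the control's change, 4 for the difference between Ogdh hairpins and 0 for the comparison at day 0. Figures were drawn with matplotlib 3.10.9 from tables read with pandas 2.3.3.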

Results

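The 24 libraries sample RN2 leukaemia cells at day 0, before doxycycline, and at day 4 of hairpin induction. The control hairpin shRen713 was carried by clones 2 and 7, shOgdh346 by clones 1 and 5, and shOgdh2081 by clones 3 and 5. Each clone had 2 libraries per day. Total counts ranged from 7275680 to 13232745 in the control libraries at day 0 and from 8394101 to 9612783 at day 4. With shOgdh346 they ranged from 7445472 to 18718239 at day 0 and from 8232763 to 15660295 at day 4. With shOgdh2081 they ranged from 7665099 to 12519741 at day 0 and from 7209186 to 20705468 at day 4. Unless another test is named, adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists are from camera.

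Ogdh, the target of both Ogdh hairpins, encodes the 2-oxoglutarate dehydrogenase subunit of the tricarboxylic acid (TCA) cycle complex that makes succinyl-CoA (ENSMUSG00000020456, GRCm38 chromosome 11, 6291633 to 6356642). In the control, its level was 228 ± 27.4 CPM (SD, n = 2 clones) at day 0 and 225 ± 27.8 CPM at day 4. With shOgdh346 it was 138 ± 13.8 CPM at day 0 and 44.8 ± 14.2 CPM at day 4. With shOgdh2081 it was 187 ± 30.2 CPM and 52.4 ± 23.6 CPM (SD, n = 2 clones each). On the log2 scale the change was -1.89 and -1.43 in clones 1 and 5 of shOgdh346 and -1.59 and -2.22 in clones 3 and 5 of shOgdh2081. It was -0.02 and -0.01 in the control clones. The fall beyond the control was -1.76 ± 0.18 (SE; edgeR adjusted p = 0.000400), lower in 8 of 8 comparisons of an Ogdh clone with a control clone. It was -1.64 ± 0.21 for shOgdh346 (adjusted p = 0.00114) and -1.87 ± 0.21 for shOgdh2081 (adjusted p = 0.00127). The difference between the hairpins in this fall was 0.24 ± 0.22 (adjusted p = 0.752).

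At day 4 the level of Ogdh was lower in every library of the Ogdh hairpins than in every control library. It stood at 35.0, 34.9, 52.8 and 58.0 CPM with shOgdh346, at 68.5, 70.9, 32.3 and 37.8 CPM with shOgdh2081, and at 206, 206, 237 and 253 CPM in the control. At day 0, before doxycycline, it stood at 126, 136, 146 and 150 CPM with shOgdh346, at 180, 235, 163 and 172 CPM with shOgdh2081, and at 202, 215, 245 and 250 CPM in the control, so that 1 shOgdh2081 library lay within the control's range. A two-sided exact permutation test over the 15 splits of the 6 clones into 4 and 2 gave p = 0.2 for the Ogdh difference of -65.2 CPM at day 0. The same exact permutation test gave p = 0.0667 for the difference of -177 CPM at day 4, the smallest p this design allows.

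**Figure D1:**
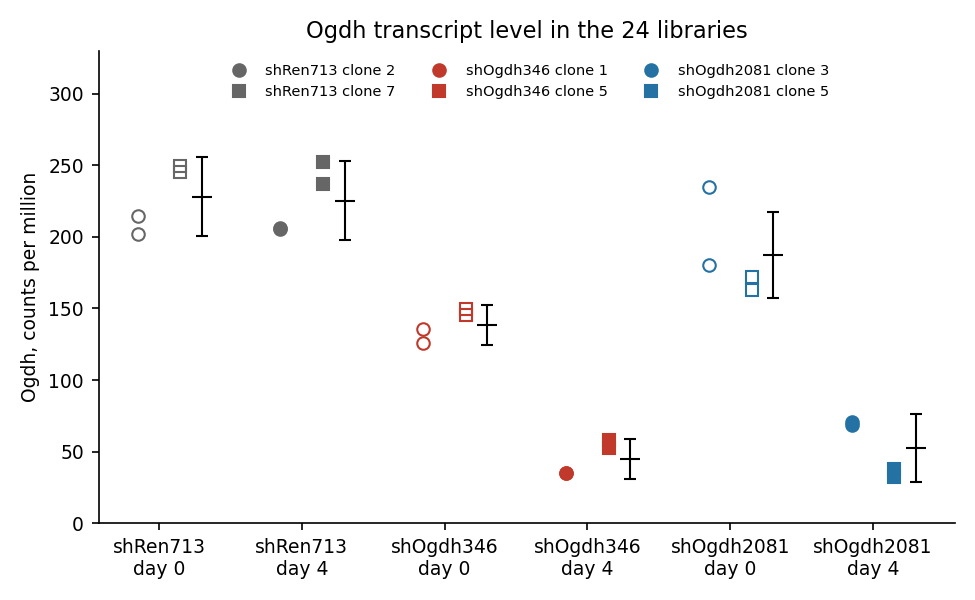
Ogdh level in CPM (vertical axis) for the 24 libraries by hairpin and day (horizontal axis), with open symbols for day 0, filled symbols for day 4, a symbol shape per clone, and black bars for the mean and SD of the 2 clones. The day 4 libraries of the Ogdh hairpins lie between 32.3 and 70.9 CPM and those of the control between 206 and 253 CPM.

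The net change, in which the control's change from day 0 to day 4 is subtracted from that of the Ogdh hairpins, asked what changed beyond the control. Among the largest rises were Retnlg and Stfa2, and among the largest falls Flt3, Cth and Pycr1. Stfa2, one of the stefins that inhibit cathepsins, went from 10.0 ± 3.81 to 865 ± 573 CPM in the Ogdh clones (SD, n = 4) and from 4.34 ± 4.08 to 3.27 ± 2.81 CPM in the control clones (SD, n = 2). Flt3, a receptor tyrosine kinase of blood progenitors, went from 11.3 ± 16.9 to 0.228 ± 0.142 CPM in the Ogdh clones and from 4.31 ± 3.66 to 2.54 ± 2.43 CPM in the control clones. By edgeR's quasi-likelihood test, 2549 genes rose and 2818 fell of 14249 tested, of which 1221 rose and 541 fell more than 2-fold.

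Retnlg, a resistin-like secreted protein of neutrophils, rose by a net log2 change of 8.88 ± 1.54 (SE, adjusted p = 0.00231), but its size and rank depended on the fit. With the day 0 libraries of replicate 2 alone it was 4.15, below Serpinb2 at 5.64, and over 40 other fits it ranged from 4.15 to 11.04. Its day 4 libraries held 1560 counts with Ogdh hairpins and 1 with the control, a ratio of 651 with a 95% counting interval of 117 to 25738. Retnlg was at 7.52 without day 0 replicate 1 of control clone 7 (adjusted p = 0.0857), at 11.04 and 8.25 without day 4 replicate 1 or 2 of that clone, and at 9.66 without day 0 replicate 2 of shOgdh2081 clone 5. Serpinb2, an inhibitor of plasminogen activators, rose by 7.35 ± 1.09 (adjusted p = 0.00120). It was at 5.77 without day 0 replicate 1 of control clone 2, where it lost its call (adjusted p = 0.0612), and at 8.18 without day 0 replicate 2 of that clone. Stfa2 rose by 6.66 ± 0.56 (adjusted p = 0.000639), Stfa3 by 5.54 ± 0.63 (adjusted p = 0.00256) and Stfa2l1 by 5.52 ± 0.23 (adjusted p = 7.18e-06). The stefin genes have near-identical copies among which reads could be shared, so the value of each one is uncertain, as is that of Raet1d below. Il1rn, the antagonist of the interleukin 1 receptor, rose by 5.96 ± 0.44 (adjusted p = 0.000166), from 3.66 ± 2.29 to 189 ± 101 CPM in the Ogdh clones (SD, n = 4). C5ar1, the receptor for complement fragment C5a, rose by 5.54 ± 0.49 (adjusted p = 0.000156), from 1.63 ± 0.187 to 46.4 ± 16.3 CPM. It was at 4.93 without control clone 2 and 7.26 without control clone 7.

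Egr1, a transcription factor of the immediate early response, rose by 5.78 ± 0.68 relative to the control (SE, adjusted p = 0.00355). Its level was 18.4 ± 7.74 CPM at day 0 and 270 ± 219 CPM at day 4 in the Ogdh clones (SD, n = 4), and 17.7 ± 4.32 and 4.13 ± 1.78 CPM in the control clones (SD, n = 2). Olfml2b, an extracellular olfactomedin-domain protein, rose by 5.60 ± 0.53 (adjusted p = 0.00137) and Col5a1, a chain of type V collagen, by 5.52 ± 0.35 (adjusted p = 2.80e-05). Raet1d, a ligand of the natural killer receptor NKG2D, rose by 5.43 ± 0.41 (adjusted p = 5.77e-05) and Ptprn, a phosphatase-like protein of secretory vesicles, by 5.56 ± 1.65 (adjusted p = 0.0495). Measured against day 0 replicate 2 alone, Egr1 was at 6.54, Col5a1 at 4.72 and Raet1d at 4.60. Ptprn was at 6.36 without day 4 replicate 1 of control clone 7 (adjusted p = 0.0616), at 7.14 without that clone and at 7.41 without shOgdh346 clone 5. Its call was also lost with RLE scaling (adjusted p = 0.0525), with the day 0 libraries of replicate 1 alone (adjusted p = 0.0816), and in each fit without 1 control library.

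Among the falls, Flt3 (ENSMUSG00000042817, chromosome 5, 147330741 to 147400489) had the largest net change at -4.01 ± 0.48 (SE, adjusted p = 0.000383), or -3.23 without shOgdh346 clone 1. Mpo, the myeloperoxidase of primary granules (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413), had a net change of -2.46 ± 0.32 (adjusted p = 0.00142). Part of this was a rise of Mpo in the control, from 1457 ± 422 to 3793 ± 974 CPM (SD, n = 2), with a log2 change of 1.39 ± 0.26 (adjusted p = 0.0281). With shOgdh346, Mpo went from 2274 ± 1874 to 461 ± 156 CPM (log2 change -2.05 ± 0.27, adjusted p = 0.000598). With shOgdh2081, Mpo was 1739 ± 1750 CPM at day 0 and 1735 ± 1843 CPM at day 4 (log2 change -0.09 ± 0.25, adjusted p = 0.778). The difference between the hairpins in Mpo did not pass (-1.96 ± 0.36, adjusted p = 0.148).

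Cth, Pycr1, Bcat1, Slc1a4 and Aldh1l2, genes of amino acid and folate metabolism, were among the 12 largest falls. Cth, which makes cysteine from cystathionine (ENSMUSG00000028179, chromosome 3, 157894248 to 157925077), fell by -3.10 ± 0.18 (SE, adjusted p = 1.77e-05). Its level went from 26.4 ± 12.5 to 3.61 ± 2.38 CPM in the Ogdh clones (SD, n = 4), against 24.5 ± 12.4 and 26.3 ± 14.3 CPM in the control clones (SD, n = 2). Pycr1, which makes proline, fell by -2.54 ± 0.20 (adjusted p = 9.23e-05), from 52.0 ± 12.9 to 7.43 ± 2.38 CPM in the Ogdh clones. Bcat1, a branched-chain aminotransferase, fell by -2.77 ± 0.63 (adjusted p = 0.0195; -3.52 without shOgdh346 clone 5 and -3.57 without shOgdh2081 clone 3) and Slc1a4, a carrier of neutral amino acids, by -2.59 ± 0.26 (adjusted p = 0.000191). Aldh1l2, a mitochondrial enzyme of folate metabolism, fell by -2.48 ± 0.32 (adjusted p = 0.000593).

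Ighm, the constant region of the IgM heavy chain, fell by -3.20 ± 0.56 (SE, adjusted p = 0.0118). Apba1, an adaptor of vesicle trafficking, fell by -3.46 ± 0.32 (adjusted p = 0.000135) and P2rx3, an ATP-gated ion channel, by -3.31 ± 0.22 (adjusted p = 3.71e-05). Serpinf1, a secreted serpin, fell by -2.86 ± 0.30 (adjusted p = 0.000224) and Bex6 by -2.82 ± 0.28 (adjusted p = 0.000178). Bex6 has similar copies, and its value is uncertain.

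**Figure D2:**
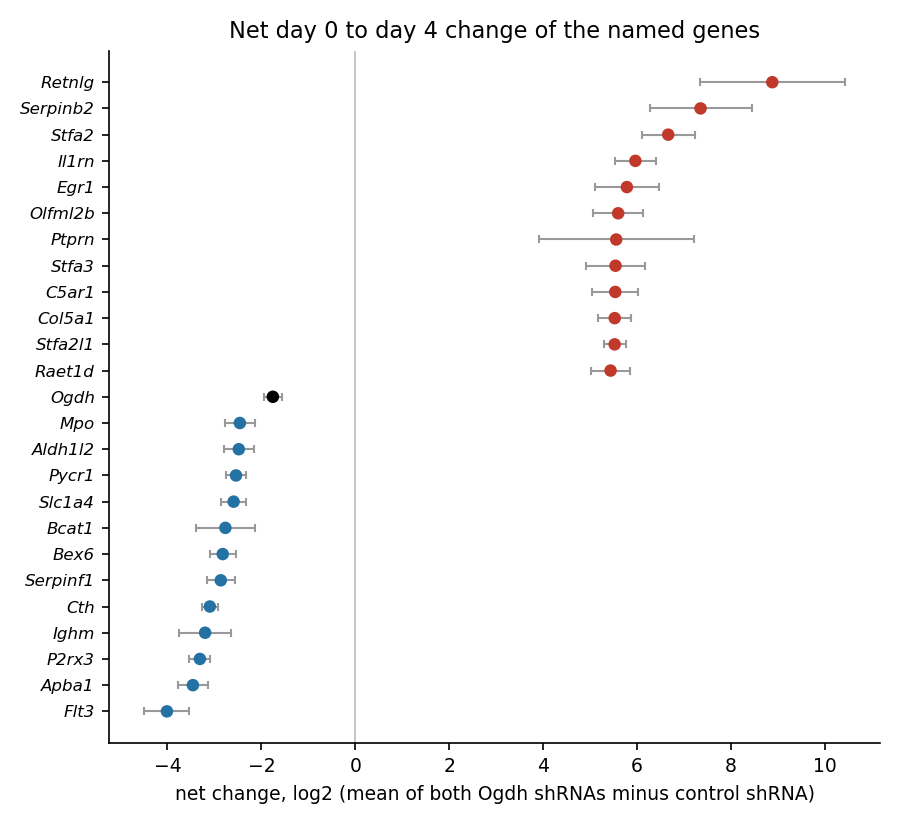
Net log2 change (horizontal axis, mean of both Ogdh hairpins minus control) of Ogdh and the 24 genes with the largest rises and falls (vertical axis), with SE as bars. The values run from -4.01 for Flt3 to 8.88 for Retnlg, the latter on a single count in the control at day 4.

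Of these 24 genes, 10 kept their call in all 40 alternative fits, among them Il1rn, C5ar1, Stfa2l1, Col5a1 and Cth, and 14 lost it in at least 1. Without the clone block 10 of the 24 lost it and the count of genes fell to 2732, and without control clone 2 or control clone 7 it came to 2392 or 2084. The highest adjusted p over the 40 fits was 0.957 for Retnlg, with the day 0 libraries of replicate 2 alone, and 0.166 for Serpinb2, without control clone 2. Without control clone 7 it was 0.0544 for Stfa2, 0.0840 for Egr1, 0.320 for Ptprn and 0.163 for Ighm. Without the block it was 0.286 for Bcat1, 0.222 for Mpo, 0.0914 for Flt3 and 0.0726 for Stfa3.

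Genes of neutrophil maturation rose together. Of 38 tested, 32 rose and 0 fell, or 34 and 0 adjusted over the list alone, with a median net log2 change of 3.16 (camera adjusted p = 5.21e-15; adjusted p = 0.397 with an estimated correlation). Chil3, a chitinase-like protein with similar copies, rose by 3.91 ± 0.14 (SE, adjusted p = 2.82e-06) and S100a9, a calcium-binding protein of neutrophil cytoplasm, by 4.67 ± 0.24 (adjusted p = 1.02e-05). Lcn2, the siderophore binder of secondary granules, rose by 5.23 ± 0.25 (adjusted p = 2.26e-05) and Itgam, the integrin subunit CD11b, by 2.07 ± 0.11 (adjusted p = 1.48e-05). Leaving out the clone block took the adjusted p of Chil3 to 0.152 and of S100a9 to 0.0612. By clone, the median change of the list from day 0 to day 4 was 3.12 and 2.85 with shOgdh346, 2.07 and 2.54 with shOgdh2081, and 0.04 and 0.01 in the control.

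Monocyte and macrophage genes gave 18 that rose and 3 that fell of 37, or 19 and 3 adjusted over the list alone, with a median of 1.36 (camera adjusted p = 0.000112; adjusted p = 0.424 with an estimated correlation). They included the chemokine Ccl6 at 4.35 ± 0.15, the membrane glycoprotein Gpnmb at 3.99 ± 0.21, the galectin Lgals3 at 3.79 ± 0.20 and the antibody receptor Fcgr4 at 2.82 ± 0.18 (SE). Gpnmb had an adjusted p of 0.127 without the clone block and was at 4.65 with the day 0 libraries of replicate 2 alone. The medians of this list and the neutrophil list were the same with members at 0 counts in a group, 6 and 3 genes, placed at their bound.

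Primary granule genes did not move as a list, with 3 that rose and 5 that fell of 14 (3 and 5 adjusted over the list alone; camera adjusted p = 0.286). Elane and Ctsg, serine proteases stored with Mpo, fell by -1.32 ± 0.19 and -1.22 ± 0.18 (SE; adjusted p = 0.00117 and 0.00119). Gfi1, a repressor needed for neutrophil formation, rose by 0.59 ± 0.11 (adjusted p = 0.00288), with an adjusted p of 0.196 without the clone block and 0.0614 without day 0 replicate 2 of control clone 2, where its value was 0.37. Genes of leukaemia self-renewal, the HOXA, MEIS1 and MYB programme, gave 3 that rose and 13 that fell of 27, or 4 and 13 adjusted over the list alone (camera adjusted p = 0.0753). The chromatin proteins Hmgb3 and Psip1 fell by -1.43 ± 0.13 and -0.88 ± 0.09, and the RNA-binding protein Igf2bp2 rose by 1.94 ± 0.22 (adjusted p = 0.295 without the clone block).

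Genes of the cell cycle fell almost without exception. Of 49 G1/S genes 48 fell and 0 rose, with a median of -0.99 (camera adjusted p = 3.33e-18; adjusted p = 0.397 with an estimated correlation). Of 52 G2/M genes 48 fell and 0 rose, with a median of -0.81 (adjusted p = 7.76e-15; adjusted p = 0.424 with an estimated correlation). Adjusted over the list alone, 48 fell in the one and 48 in the other. The helicase Hells and the replication licensing factor Cdc6 fell by -1.20 ± 0.09 and -1.26 ± 0.10 (SE; adjusted p = 5.38e-05 and 5.77e-05). The mitotic genes Cenpf and Ccnb1 fell by -1.39 ± 0.09 and -1.03 ± 0.09 (adjusted p = 2.75e-05 and 0.000111).

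MYC targets and ribosome biogenesis genes gave 41 that fell and 0 that rose of 48 (46 and 0 adjusted over the list alone), with a median of -0.68 (camera adjusted p = 1.07e-12; adjusted p = 0.445 with an estimated correlation). Among them were Polr1b of RNA polymerase I at -1.08 ± 0.10 and Dkc1, which modifies ribosomal RNA, at -1.11 ± 0.12 (SE). Purine and pyrimidine synthesis genes gave 23 that fell and 0 that rose of 29 (24 and 0 adjusted over the list alone), with a median of -0.92 (adjusted p = 1.53e-08; adjusted p = 0.397 with an estimated correlation). They included thymidine kinase Tk1 at -1.10 ± 0.09. The replication-dependent histones, whose near-identical copies make single values uncertain, were not called as a list (2 rose and 0 fell of 12, or 2 and 0 adjusted over the list alone; adjusted p = 0.310).

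Targets of ATF4 and the integrated stress response and genes of serine and one-carbon metabolism, which share members, were lower as lists. Of 34 ATF4 targets 6 rose and 23 fell, or 7 and 24 adjusted over the list alone, with a median of -0.89 (camera adjusted p = 0.000112; adjusted p = 0.496 with an estimated correlation). Asparagine synthetase Asns fell by -2.00 ± 0.12 (SE, adjusted p = 2.26e-05) and the mitochondrial carboxykinase Pck2 by -1.68 ± 0.11 (adjusted p = 3.00e-05). Of 21 serine and one-carbon genes 1 rose and 17 fell, or 1 and 17 adjusted over the list alone, with a median of -0.96 (adjusted p = 7.22e-06; adjusted p = 0.397 with an estimated correlation). The folate enzymes Shmt2 and Mthfd2 fell by -1.63 ± 0.14 and -1.24 ± 0.12.

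Glutamate, glutamine and aspartate metabolism gave 0 genes that rose and 10 that fell of 25, or 0 and 12 adjusted over the list alone (median -0.32; camera adjusted p = 0.00525; adjusted p = 0.397 with an estimated correlation). The aminotransferases Gpt2 and Oat fell by -1.47 ± 0.11 and -1.01 ± 0.10 (SE). Branched-chain amino acid breakdown gave 3 that rose and 7 that fell of 20, or 3 and 9 adjusted over the list alone (median -0.38; adjusted p = 0.0322; adjusted p = 0.496 with an estimated correlation). There Bckdk, Mut and Acad8 fell by -0.85 ± 0.11, -0.73 ± 0.11 and -0.85 ± 0.13 and Acadsb rose by 0.76 ± 0.12. The branched-chain list's adjusted p was 0.0583 with the day 0 libraries of replicate 2 alone, within a range of 0.00620 to 0.0583 over the other fits with camera's preset correlation.

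The TCA cycle list gave 14 genes that fell and 0 that rose of 23, or 14 and 0 adjusted over the list alone, with a median of -0.40 (camera adjusted p = 8.22e-05; adjusted p = 0.424 with an estimated correlation). Fumarase Fh1 fell by -1.01 ± 0.12 (SE, adjusted p = 0.000359), Idh3a, a subunit of NAD-dependent isocitrate dehydrogenase, by -0.82 ± 0.11 (adjusted p = 0.000750), and pyruvate carboxylase Pcx by -1.25 ± 0.18 (adjusted p = 0.000893). Of 12 genes of the 2-oxoacid dehydrogenase complexes, Ogdh among them, 4 fell and 0 rose, or 4 and 1 adjusted over the list alone (median -0.41; adjusted p = 0.0172; adjusted p = 0.424 with an estimated correlation). The others that fell were Pdhb, Pdhx and Dlat of pyruvate dehydrogenase at -0.49 ± 0.08, -0.55 ± 0.12 and -0.39 ± 0.09. Leaving out control clone 2 took their adjusted p to 0.0531, 0.117 and 0.0706, and that of Dlat was 0.148 without control clone 7.

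Nuclear genes of the respiratory chain gave 32 that fell and 2 that rose of 71 (37 and 2 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 1.41e-06; adjusted p = 0.509 with an estimated correlation; fry adjusted p = 0.0562). The complex I subunits Ndufv1 and Ndufa5 fell by -0.65 ± 0.10 and -0.87 ± 0.13 (SE). Of the 7 respiratory chain genes of mitochondrial DNA none passed by edgeR's test, also adjusted over the list alone (camera adjusted p = 0.926), with mt-Co1 at 0.41 ± 0.15 and mt-Nd1 at -0.41 ± 0.15. Mitochondrial ribosomal protein genes gave 46 that fell and 0 that rose of 74, or 56 and 0 adjusted over the list alone (median -0.42; adjusted p = 6.22e-11; adjusted p = 0.424 with an estimated correlation), with Mrpl33 at -1.03 ± 0.10 (adjusted p = 0.0678 without the clone block). The mitochondrial unfolded protein response and proteostasis list gave 10 that fell and 1 that rose of 17, or 11 and 1 adjusted over the list alone (median -0.50; adjusted p = 0.00147; adjusted p = 0.397 with an estimated correlation). Its chaperones Hspd1 and Trap1 fell by -1.01 ± 0.13 and -0.93 ± 0.12.

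Glycolysis genes rose in part, with 14 that rose and 1 that fell of 24 (15 and 2 adjusted over the list alone) and a median of 0.38 (camera adjusted p = 0.000773; adjusted p = 0.496 with an estimated correlation). The glucose carriers Slc2a3 and Slc2a1 rose by 5.07 ± 0.55 and 1.20 ± 0.18 and the lactate carrier Slc16a3 by 1.96 ± 0.19 (SE; adjusted p = 0.000311, 0.00161 and 0.000377), with 0.134 for Slc2a3 without the clone block. Without control clone 7 Slc2a3 was at 6.32. Hypoxia-inducible factor targets, 12 of whose 23 tested genes are also in another list, gave 15 that rose and 0 that fell, or 15 and 0 adjusted over the list alone (median 0.56; adjusted p = 0.000112; adjusted p = 0.397 with an estimated correlation). Among them were adenylate kinase Ak4 at 3.53 ± 0.39 and Ndrg1 at 1.05 ± 0.15. Ak4 lost its call in 5 of 40 other fits (adjusted p = 0.179 without the clone block, and 0.0947 without day 0 replicate 1 of control clone 2, at 2.84). Ak4 was at 2.91 without day 0 replicate 1 of control clone 7 and 4.61 without that of shOgdh346 clone 1. The dioxygenases that use 2-oxoglutarate, which include histone and DNA demethylases, went both ways, with 10 that rose and 6 that fell of 41, or 12 and 6 adjusted over the list alone (median 0.09; adjusted p = 0.287). The histone demethylase genes Kdm6b, Kdm7a and Kdm3a rose by 1.57 ± 0.09, 1.23 ± 0.12 and 0.79 ± 0.12 and Kdm8 fell by -0.77 ± 0.16. The adjusted p of Kdm7a was 0.0949 without the clone block and that of Kdm8 0.0934 without control clone 2.

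Cholesterol synthesis genes gave 11 that fell and 0 that rose of 24, or 13 and 0 adjusted over the list alone (median -0.50; camera adjusted p = 8.22e-05; adjusted p = 0.496 with an estimated correlation; fry adjusted p = 0.0834). Acat2 and Mvk fell by -1.46 ± 0.14 and -1.30 ± 0.15 (SE). Fatty acid synthesis gave 2 that rose and 7 that fell of 17, or 2 and 7 adjusted over the list alone (adjusted p = 0.176), with Fasn, the synthase itself, at -0.98 ± 0.14 and the elongase Elovl6 at -1.12 ± 0.14. Fatty acid oxidation gave 3 that rose and 8 that fell of 23, or 3 and 8 adjusted over the list alone (adjusted p = 0.478), with Crat at 0.73 ± 0.10 and Hadh at -0.63 ± 0.11. The sign of that list's median depended on the scaling. Adjusted p was 0.0551 for Fasn and 0.266 for Elovl6 without the clone block, and 0.0584 for Hadh without control clone 7.

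Immediate early and inflammatory genes were higher relative to the control. Immediate early genes gave 20 that rose and 1 that fell of 33 (21 and 1 adjusted over the list alone), with a median of 1.34 (camera adjusted p = 2.58e-05; adjusted p = 0.452 with an estimated correlation). Among them were the ERK phosphatase genes Dusp5 and Dusp6 at 1.69 ± 0.19 and 1.44 ± 0.16 (SE). NF-kB and inflammatory genes gave 12 that rose and 2 that fell of 18, or 13 and 2 adjusted over the list alone (median 1.65; adjusted p = 0.000205; adjusted p = 0.496 with an estimated correlation), with Nfkbia at 1.68 ± 0.12 and Icam1 at 1.25 ± 0.17. Lysosome and autophagy genes gave 18 that rose and 0 that fell of 32, or 18 and 0 adjusted over the list alone (median 0.56; adjusted p = 2.03e-06; adjusted p = 0.452 with an estimated correlation). The autophagy receptor Sqstm1 and cathepsin L, Ctsl, rose by 1.45 ± 0.10 and 2.13 ± 0.20 (adjusted p = 0.113 for Ctsl without the clone block).

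Stress lists went up or down by pathway. Targets of p53 gave 10 that rose and 0 that fell of 25, or 10 and 0 adjusted over the list alone (median 0.65; camera adjusted p = 0.000281; adjusted p = 0.496 with an estimated correlation), with Mdm2 at 1.14 ± 0.14 and Gadd45a at 1.18 ± 0.16 (SE). NRF2 targets gave 10 that rose and 3 that fell of 21, or 11 and 3 adjusted over the list alone (median 0.42; adjusted p = 0.0356; adjusted p = 0.397 with an estimated correlation). Ferritin heavy chain Fth1, sulfiredoxin Srxn1 and glutathione reductase Gsr rose by 1.30 ± 0.18, 1.08 ± 0.18 and 0.77 ± 0.13, with an adjusted p without the clone block of 0.0515 for Srxn1 and 0.131 for Gsr. Without control clone 7 the NRF2 list's adjusted p was 0.0698, within 0.0112 to 0.0698 over the other fits with the preset correlation. The endoplasmic reticulum unfolded protein response gave 2 that rose and 13 that fell of 20, or 3 and 14 adjusted over the list alone (median -0.57; adjusted p = 0.0165; adjusted p = 0.607 with an estimated correlation; fry adjusted p = 0.140). There Herpud1 fell by -1.02 ± 0.14 and Edem1 rose by 0.82 ± 0.12 (adjusted p = 0.137 without the clone block).

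Apoptosis regulators went both ways, with 12 that rose and 8 that fell of 32, or 14 and 9 adjusted over the list alone (camera adjusted p = 0.145). The survival gene Bcl2l1 and the death gene Bcl2l11 rose by 1.45 ± 0.11 and 2.23 ± 0.19 and the survival gene Bcl2 fell by -0.87 ± 0.11 (SE). Interferon-stimulated genes gave 7 that rose and 4 that fell of 36, or 4 and 3 adjusted over the list alone (adjusted p = 0.242), with the RNA sensor Ddx58 at 2.33 ± 0.25 and Ifit2 at -0.98 ± 0.16 (adjusted p = 0.0775 for Ifit2 without the clone block). MHC class II and antigen presentation gave 4 that rose and 5 that fell of 13, or 4 and 5 adjusted over the list alone (adjusted p = 0.940). There Cd74, the class II invariant chain, rose by 3.89 ± 0.73 and the immunoproteasome subunits Psmb8 and Psmb9 fell by -1.01 ± 0.16 and -1.14 ± 0.19. Cd74 was near the floor, and part of its net rise was a log2 change of -2.19 in the control, from 16 counts to 3 over the group. It went from 32 to 58 counts with shOgdh346 and from 6 to 43 with shOgdh2081. Cd74 had an adjusted p of 0.244 without control clone 7, at 2.95, and of 0.132 with the day 0 libraries of replicate 2 alone, at 2.58. Without day 0 replicate 1 of control clone 7 Cd74 was at 3.22. Cytosolic ribosomal protein genes, whose reads could be shared with processed copies, gave 10 that fell and 0 that rose of 75, but 0 of either adjusted over the list alone by edgeR's test. The list had a median of -0.21 (camera adjusted p = 0.00106; adjusted p = 0.718 with an estimated correlation; fry adjusted p = 0.340), with Rpl22 at -0.49 ± 0.13 (adjusted p = 0.122 without control clone 2 and 0.115 without control clone 7).

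Markers of other cell types were also measured. Megakaryocyte and platelet genes gave 5 that rose and 0 that fell of 7, or 7 and 0 adjusted over the list alone (median 1.72; camera adjusted p = 0.000476; adjusted p = 0.397 with an estimated correlation), among them Vwf at 3.11 ± 0.46 and Itga2b at 2.87 ± 0.53 (SE). Stromal and epithelial genes gave 3 that rose and 0 that fell of 6, also adjusted over the list alone. Their median was 1.98 (adjusted p = 0.0286, or 0.397 with an estimated correlation). Acta2 was at 3.27 ± 0.58 and Pdgfrb, no higher at day 4 than day 0 with shOgdh346, at 0.69 ± 0.15. Col1a1 and Epcam had only 1 to 8 counts per group at day 0. Itga2b and Pdgfrb lost their calls without control clone 2 or 7. Without the block adjusted p was 0.0713 for Vwf and 0.795 for Pdgfrb. Vwf was at 2.41 without day 0 replicate 1 of control clone 7 and 2.44 without that clone. With 24 libraries and the replicate number as a block the stromal list's adjusted p was 0.0629, within 0.0132 to 0.0629 over the other fits with the preset correlation.

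Mast cell, basophil and eosinophil genes gave 2 that rose and 0 that fell of 7, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.290), the 2 being Gata2 at 0.57 ± 0.13 and Hdc at 2.46 ± 0.66 (SE). T and NK cell genes gave 2 that rose of 7, Il7r at 3.41 ± 0.60 and Prf1 at 4.16 ± 1.01, or 2 adjusted over the list alone (adjusted p = 0.124). B cell genes gave 1 that fell of 7, Rag2 at -2.86 ± 0.77, or 1 adjusted over the list alone (adjusted p = 0.606). Dendritic cell genes gave 1 that rose and 3 that fell of 6, or 1 and 3 adjusted over the list alone (adjusted p = 0.152), with Itgax at 3.03 ± 0.50, Tcf4 at -0.47 ± 0.10 and Xcr1 at -2.41 ± 0.79. These single genes were sensitive to the fit. Hdc lost its call in 18 of 40 other fits (adjusted p up to 0.299, without control clone 2) and Xcr1 in 18 of 36 (up to 0.406, without control clone 7). Prf1 and Rag2 lost it in 4 of 37 each, with 0.319 for Prf1 without control clone 2 and 0.150 for Rag2 without control clone 7. Prf1 was at 3.59 without day 0 replicate 2 of control clone 2 (adjusted p = 0.0662), at 3.49 and 5.51 without day 4 replicate 1 or 2 of that clone, and at 5.25 without day 0 replicate 1 of shOgdh346 clone 5. Rag2 was at -2.06 without shOgdh346 clone 1 and -3.61 without shOgdh346 clone 5. Without control clone 7 adjusted p was 0.154 for Gata2, at 0.38, 0.0714 for Itgax and 0.0759 for Tcf4, and without control clone 2 it was 0.0798 for Il7r, at 2.49. Of the 14 erythroid genes only Tfr2, Gata1 and Klf1 passed the filter, of which 1 rose, and that list was not tested. In all, camera called 11 lists higher and 16 lower of 41, fry called 28, of which camera had called 23, and an estimated correlation left 0, with a lowest adjusted p of 0.397. The estimated correlation rests on 3 residual degrees of freedom, and with it camera called 0 lists in every change tested. Its lack of calls therefore cannot tell lists that moved from those that did not.

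**Figure D3:**
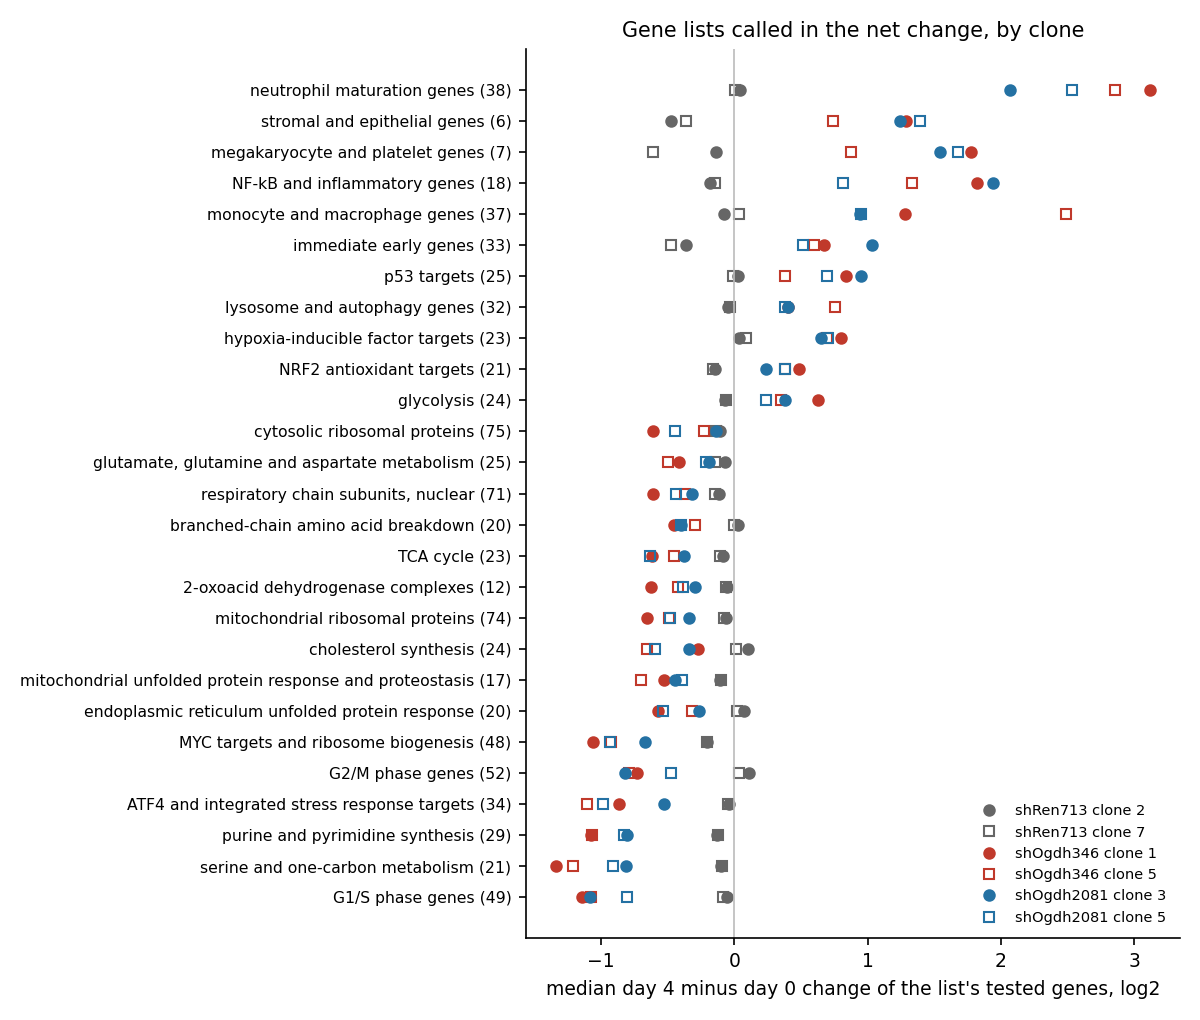
Median log2 change from day 0 to day 4 (horizontal axis) of the members of each of the 27 gene lists called by camera (vertical axis), with a point per clone coloured by hairpin. The neutrophil maturation list lies between 2.07 and 3.12 in the 4 Ogdh clones and at 0.04 and 0.01 in the control clones.

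Each hairpin was also set against the control on its own, to ask whether the 2 hairpins change the same genes. The neutrophil gene Retnlg and the serpin Serpinb2 were among the largest rises with either hairpin, and Flt3 among the largest falls.

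With shOgdh346, 2339 genes rose and 2626 fell by edgeR's quasi-likelihood test. Retnlg rose by 10.03 ± 1.62, Stfa2 by 6.93 ± 0.59, Serpinb2 by 6.51 ± 1.16 and Il1rn by 6.37 ± 0.48 (SE; adjusted p = 0.00184, 0.000787, 0.00320 and 0.000225). Flt3 fell by -5.00 ± 0.54, Cth by -3.69 ± 0.22, Aldh1l2 by -3.60 ± 0.39 and Mpo by -3.44 ± 0.37 (adjusted p = 0.000298, 2.42e-05, 0.000297 and 0.000844). The count of genes was 2296 without the clone block, 2375 without control clone 2 and 2108 without control clone 7. Over 30 other fits, 3 of these 8 genes kept their calls (Il1rn, Cth and Aldh1l2), and adjusted p reached 0.975 for Retnlg, 0.255 for Serpinb2, 0.0514 for Stfa2 and 0.0781 for Flt3. With the day 0 libraries of replicate 2 alone Retnlg was at 5.37 and Serpinb2 at 4.22. Retnlg was at 8.67 without day 0 replicate 1 of control clone 7 (adjusted p = 0.0670), and at 12.19 and 9.40 without day 4 replicate 1 or 2 of that clone. Serpinb2 was at 4.93 without day 0 replicate 1 of control clone 2 (adjusted p = 0.0994), at 7.33 without day 0 replicate 2 of that clone and at 5.77 without day 0 replicate 1 of shOgdh346 clone 1. Without shOgdh346 clone 1 Retnlg was at 7.82, Serpinb2 at 4.57, Il1rn at 5.57, Flt3 at -3.43 and Mpo at -2.84. Between day 4 groups the 142 counts of Serpinb2 with shOgdh346 against 4 in the control were a ratio of 30.5 (95% counting interval 11.7 to 114).

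With shOgdh2081, 1933 genes rose and 2025 fell. Serpinb2 rose by 8.19 ± 1.10, Retnlg by 7.73 ± 1.55, Stfa2 by 6.39 ± 0.60 and Egr1 by 5.95 ± 0.75 (SE; adjusted p = 0.00160, 0.00716, 0.00179 and 0.00688). Apba1 fell by -3.92 ± 0.43, Ighm by -3.75 ± 0.66, P2rx3 by -3.18 ± 0.26 and Flt3 by -3.02 ± 0.63 (adjusted p = 0.000647, 0.0177, 0.000197 and 0.00833). The count of genes was 1212 without the clone block, 1363 without control clone 2 and 1118 without control clone 7. Of these 8 genes 0 kept their calls over 30 other fits, and adjusted p reached 0.937 for Retnlg, 0.171 for Serpinb2, 0.0806 for Stfa2 and 0.331 for Flt3. Measured against day 0 replicate 2 alone, Retnlg was at 2.93 and Serpinb2 at 7.06. Serpinb2 was at 6.62 without day 0 replicate 1 of control clone 2 (adjusted p = 0.0548) and at 9.02 without day 0 replicate 2 of that clone. Retnlg was at 6.37 without day 0 replicate 1 of control clone 7 (adjusted p = 0.145), at 9.88 and 7.09 without day 4 replicate 1 or 2 of that clone, and at 9.30 without day 0 replicate 2 of shOgdh2081 clone 5. Without shOgdh2081 clone 5 Retnlg was at 11.96 and Stfa2 at 7.08, and without shOgdh2081 clone 3 Flt3 was at -3.90. Apba1 was at -5.00 without day 4 replicate 1 of shOgdh2081 clone 3.

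The hairpins shared 1610 genes that were higher and 1766 that were lower under both, with 1 changed in opposite directions, against 317 and 373 for independent lists. Across 9582 genes, which are not independent replicates, the net changes correlated at r = 0.93 with a covariance of 0.469. The same control libraries stand in both, and simulated groups with no effect gave r = 0.51 and a covariance of 0.0231 (mean of 20 sets). With the control clones split between the hairpins the covariance was 0.460 or 0.462, with r = 0.90 or 0.91. The changes from day 0 to day 4, which share no library, correlated at r = 0.94 with a covariance of 0.523. In these, 3343 genes were higher and 3254 lower under both and 13 opposite, against 1182 and 1082 for independent lists. Between pairs of Ogdh clones r was 0.88 to 0.93, between an Ogdh clone and a control clone 0.23 to 0.36, and between the control clones 0.84. Without the clone block 1061 genes were shared, without control clone 2 1205 and without control clone 7 1001.

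**Figure D4:**
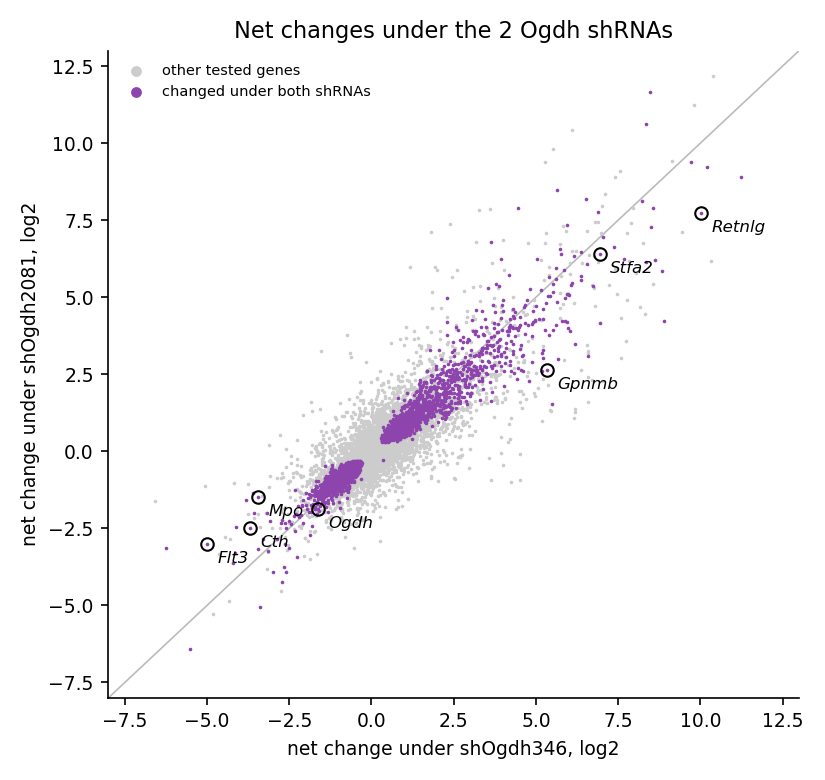
Net log2 change with shOgdh346 (horizontal axis) against that with shOgdh2081 (vertical axis) for the genes tested, with a point per gene, purple for genes changed under both, and the diagonal as a line. The changes correlate at r = 0.93 across the 9582 genes used for that value, against 0.51 in simulated groups that share controls and have no effect.

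The test of the difference between the hairpins asked which genes they change unequally. Few genes differed, among them Gpnmb, Tgm2, Zbtb16 and Angpt1. Gpnmb, a glycoprotein of macrophages, went from 12.2 ± 13.9 to 504 ± 600 CPM with shOgdh346 and from 4.72 ± 2.00 to 28.4 ± 7.82 CPM with shOgdh2081 (SD, n = 2 clones). By edgeR's quasi-likelihood test 8 genes were higher and 7 lower with shOgdh346 than with shOgdh2081. Gpnmb differed by 2.69 ± 0.22 on the log2 scale (SE, adjusted p = 0.00571) and Wfdc17, a secreted protein with similar copies, by 3.51 ± 0.30 (adjusted p = 0.00571). The crosslinking enzyme Tgm2 differed by 2.73 ± 0.26 (adjusted p = 0.0116; 5.11 with the day 0 libraries of replicate 2 alone) and the endocytic adaptor Dab2 by 2.21 ± 0.29 (adjusted p = 0.0309). In the other direction were the zinc finger regulator Zbtb16 at -2.02 ± 0.23 (adjusted p = 0.0245) and the vascular ligand Angpt1 at -1.67 ± 0.22 (adjusted p = 0.0309). The growth factor receptor Pdgfrb was at -1.35 ± 0.17 (adjusted p = 0.0309) and the actin-binding calponin Cnn3 at -1.27 ± 0.15 (adjusted p = 0.0245). At an unadjusted p under 0.05 there were 1421 genes, against 712 by chance.

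Angpt1 went from 30.0 ± 15.9 to 10.8 ± 8.84 CPM with shOgdh346 and from 42.4 ± 5.47 to 44.7 ± 4.37 CPM with shOgdh2081 (SD, n = 2 clones), and Pdgfrb from 20.2 ± 2.06 to 18.4 ± 3.66 and from 16.1 ± 17.6 to 37.4 ± 41.2 CPM. By camera, 5 lists were higher and 10 lower with shOgdh346 than with shOgdh2081, while fry called 0. Higher were neutrophil maturation (median 0.41, adjusted p = 4.68e-06), monocyte and macrophage genes (0.42, adjusted p = 3.16e-05) and interferon-stimulated genes (0.42, adjusted p = 3.16e-05). Glycolysis and lysosome genes were higher with adjusted p = 0.00106 and 0.00149. Lower were serine and one-carbon metabolism (-0.35, adjusted p = 3.16e-05) and ATF4 targets (-0.32, adjusted p = 0.000207), and the cell cycle, MYC, ribosomal, respiratory chain, nucleotide and glutamate lists. All 15 lost their call by camera with an estimated correlation (adjusted p = 0.863 to 0.883), which called 0 lists in every change.

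The count of 15 genes that differ between the hairpins, Gpnmb and Zbtb16 among them, depended on the fit. It was 0 without the clone block, 101 by DESeq2 (75 higher and 26 lower), 20 with RLE scaling (13 and 7) and 23 with upper-quartile scaling (16 and 7). It was 692 with 24 libraries and a clone block and 347 with the replicate number as a block. Without shOgdh2081 clone 5 it was 8 and without shOgdh346 clone 5 it was 59. Leaving out 1 library gave 2 (without day 0 replicate 1 of shOgdh2081 clone 3) to 38 (without day 0 replicate 1 of shOgdh346 clone 5). The 2 were Wfdc17 at 3.67 and Zbtb16 at -2.12, chosen after their values were seen. All 8 named genes lost their call in at least 1 of 30 other fits, all 8 of them without the clone block.

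The control's own change from day 0 to day 4 was tested to ask which genes changed without Ogdh knockdown. Fosb and Klf2, genes of the immediate early response, fell. Fosb, a subunit of the AP-1 transcription factor, went from 8.08 ± 6.47 to 0.290 ± 0.0977 CPM (SD, n = 2), a log2 change of -4.64 ± 0.49 (SE, edgeR quasi-likelihood adjusted p = 0.00314). Klf2, a zinc finger factor, went from 9.04 ± 6.25 to 1.65 ± 0.953 CPM (-2.42 ± 0.22, adjusted p = 0.00215). The related factor Klf11 fell by -1.83 ± 0.28 (adjusted p = 0.0124) and the arrestin family member Arrdc3 by -1.67 ± 0.15 (adjusted p = 0.00215). Klf11 was at 20.8 ± 5.59 and 5.89 ± 2.16 CPM in the control, and at 19.3 ± 3.13 and 5.74 ± 2.38 CPM in the Ogdh clones (SD, n = 4). With the day 0 libraries of replicate 2 alone Klf2 was at -1.75, Klf11 at -0.93 (adjusted p = 0.147) and Arrdc3 at -0.76 (adjusted p = 0.0642). Fosb was at -3.26 without clone 7 (adjusted p = 0.0981) and at -5.80 without clone 2. Klf11 lost its call in 6 of 20 other fits, with an adjusted p of up to 0.227 (without clone 7). Without day 0 replicate 1 of clone 7 adjusted p was 0.165 for Klf11 and 0.0840 for Arrdc3, and without day 0 replicate 1 of clone 2 it was 0.0563 for Klf11.

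The largest rises in the control were Clec2d, a C-type lectin ligand of natural killer receptors (1.94 ± 0.20, SE, adjusted p = 0.00273), and the zinc finger genes Zfp780b (1.59 ± 0.18, adjusted p = 0.00370) and Zfp60 (1.58 ± 0.16, adjusted p = 0.00273). The annotated microRNA gene Mir6236 rose by 1.52 ± 0.30 (adjusted p = 0.0401). It lost its call in 8 of 20 other fits, among them those without day 0 replicate 1 of clone 2 or clone 7 (adjusted p = 0.0561 and 0.208) and without day 4 replicate 1 of clone 2 or clone 7 (0.142 and 0.141). Without day 4 replicate 2 of clone 2 it was at 0.82. With the day 0 libraries of replicate 1 alone Clec2d was at 3.13 and Zfp60 at 2.23, and with those of replicate 2 alone Clec2d was at 1.18. Without clone 7 adjusted p was 0.0736 for Clec2d and 0.104 for Zfp780b and for Zfp60. These 4 belong to families of similar copies or to repeats, and their values are uncertain. In all, 633 genes rose and 347 fell, of which 116 and 117 changed more than 2-fold. Of the genes changed both here and in the net change, 116 went up in both, 61 down in both and 249 opposite ways, against 113 up and 68.6 down for independent lists. The control's change is subtracted in the net change, so shared libraries push these lists apart by construction.

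As a list, 6 of 33 immediate early genes fell in the control and 0 rose, or 7 and 0 adjusted over the list alone (median -0.42; camera adjusted p = 8.31e-05; adjusted p = 0.946 with an estimated correlation). The phosphatase genes Dusp1 and Dusp2 fell by -1.10 ± 0.19 and -0.75 ± 0.14 (SE). Of 20 other fits Dusp1 lost its call in 7, Dusp2 in 6, Myc in 8 and Hmox1 in 5. Without clone 7 adjusted p was 0.413 for Dusp1, 0.226 for Dusp2, 0.274 for Myc and 0.155 for Hmox1. Measured against day 0 replicate 2 alone, Dusp1 was at -0.44 and Myc at 0.18. Camera called 6 other lists lower, each with adjusted p = 0.946 with an estimated correlation, in which at most 1 gene rose and 1 fell. They were MYC targets (adjusted p = 8.31e-05, with Myc itself higher at 0.64 ± 0.10), nuclear respiratory chain genes (adjusted p = 0.000587) and cytosolic ribosomal proteins (adjusted p = 0.00337). NRF2 targets, with Hmox1 at -0.63 ± 0.08, nucleotide synthesis and MHC class II each had adjusted p = 0.0417. Fry called 0 lists in the control.

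At day 0, replicate 2 libraries differed from replicate 1 libraries of the same clone in 5092 of 11684 genes, among them Jun at -2.06 and Klf11 at -1.40 on the log2 scale, against 924 of 12248 genes at day 4. With the day 0 libraries of replicate 1 alone the control's count of changed genes was 1978 and with those of replicate 2 alone 122. It was 8 without clone 7, 17 without clone 2, 189 without day 0 replicate 1 of clone 7, 239 without day 0 replicate 1 of clone 2, 1476 without day 0 replicate 2 of clone 2, and 147 without the clone block. All 8 named genes lost their call in at least 1 of 20 other fits, with adjusted p of up to 0.0981 for Fosb and 0.104 for Klf2 (both without clone 7) and 0.0840 for Arrdc3 (without day 0 replicate 1 of clone 7).

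Within each Ogdh hairpin, day 4 was set against day 0 to give the change in the cells as they were. With shOgdh346, Car4, a membrane-bound carbonic anhydrase, went from 0 counts to 287 over its 4 libraries, at least 96.6-fold higher, and with shOgdh2081 from 0 to 1848, at least 532-fold higher. Mmp9, the gelatinase of neutrophil granules, rose by 6.78 ± 0.84 with shOgdh346 and by 6.37 ± 0.86 with shOgdh2081 (SE; edgeR quasi-likelihood adjusted p = 0.00204 and 0.00331). Over 20 other fits Mmp9 ranged from 4.87 (without clone 1) to 8.21 (day 0 replicate 1 alone) with shOgdh346, and from 4.43 (without clone 3) to 8.05 (without clone 5) with shOgdh2081. It was at 5.77 without day 0 replicate 1 of shOgdh346 clone 1 and 6.99 without that of shOgdh2081 clone 5. With shOgdh346, Retnlg rose by 8.04 ± 0.46 (adjusted p = 3.51e-06), a ratio of 212 by counts with a 95% interval of 97.2 to 579, and Tgm2 by 7.51 ± 0.16 (adjusted p = 3.11e-08). Flt3 fell by -5.81 ± 0.40, Serpinf1 by -3.75 ± 0.27, Cth by -3.60 ± 0.17 and P2rx3 by -3.56 ± 0.21 (adjusted p = 6.84e-06, 8.15e-06, 1.46e-06 and 3.64e-06). With shOgdh2081, Serpinb2 rose by 6.60 ± 0.24 and Stfa2l1 by 6.11 ± 0.18 (adjusted p = 1.38e-06 and 3.98e-07). Ighm fell by -4.38 ± 0.52, Flt3 by -3.82 ± 0.50, Serpinf1 by -3.71 ± 0.27 and the Wnt ligand Wnt10b by -3.63 ± 0.65 (adjusted p = 0.00222, 0.000284, 1.54e-05 and 0.00354). Without shOgdh346 clone 1 Retnlg was at 5.84 and Flt3 at -4.22, and without shOgdh2081 clone 3 Flt3 was at -4.69. With the day 0 libraries of replicate 2 alone Tgm2 was at 10.96 with shOgdh346 and Serpinb2 at 7.69 with shOgdh2081. In all, 4302 genes rose and 4174 fell with shOgdh346, and 3914 rose and 3693 fell with shOgdh2081. Over 20 other fits the adjusted p reached 0.120 for Car4 with shOgdh346 and 0.0663 with shOgdh2081 (both by DESeq2), 0.0703 for Flt3 with shOgdh2081 (without the clone block) and 0.0801 for Wnt10b (without clone 3).

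At day 0, before doxycycline, the comparison of the Ogdh hairpins with the control asked whether the 4 Ogdh clones differed as a group from the 2 control clones. Ogdh itself was 163 ± 34.2 CPM in the Ogdh clones (SD, n = 4) and 228 ± 27.4 CPM in the control clones (SD, n = 2), a log2 difference of -0.50 ± 0.27 (SE) that did not pass. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes passed, with 272 at an unadjusted p under 0.05 against 712 by chance. DESeq2 called 2, the lactate carrier Slc16a3 at -0.99 and the protease inhibitor Serpine2 at -1.38, each with an adjusted p of 0.0289. Serpine2 was also among 4 genes called lower with 24 single libraries, with the hexokinase gene Hk1 at -0.35, Abhd8 at -0.42 and the predicted gene Gm26880 at -4.04. With no filter 1 gene passed (Gm26880), and with the replicate number as a block of 24 libraries 8 did. Without control clone 7, 3 did (Smg9 at -2.73, Lrrk2 at -9.07 and 5730507C01Rik at 9.46), and without shOgdh2081 clone 5 1 did, the myelin gene Mbp at -2.04. These genes are named after their values were seen.

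At day 4, the Ogdh hairpins were set against the control directly, to ask how the cells differed after induction. Retnlg and Stfa2 were higher and Flt3 lower. Car4 had 0 counts in the control and 2135 with Ogdh hairpins, at least 297-fold higher. By edgeR's quasi-likelihood test, Retnlg was higher by 8.80 ± 1.75, Stfa2 by 7.89 ± 0.89 and Serpinb2 by 7.63 ± 1.13 on the log2 scale (SE; adjusted p = 0.00605, 0.000610 and 0.00180). Apba1 differed by -3.55 ± 0.80, Flt3 by -3.47 ± 1.07, P2rx3 by -3.44 ± 0.73 and B3gnt5, an enzyme of glycosphingolipid synthesis, by -3.34 ± 0.60 (adjusted p = 0.00988, 0.0339, 0.00786 and 0.00367). In all, 2487 genes were higher and 3015 lower. Of these, 1908 were also higher and 2434 also lower in the net change, which shares the day 4 libraries, and 0 went the opposite way, against 445 and 596 for independent lists. Without control clone 2 the count was 3089 and without control clone 7 2905. Over 27 other fits the adjusted p reached 0.229 for Car4 (no filter), 0.0770 for Retnlg (without control clone 2) and 0.322 for Flt3 (without control clone 7). It reached 0.0598 for Apba1 (without shOgdh2081 clone 5) and 0.0511 for P2rx3 (without shOgdh2081 clone 3). Without control clone 7 Flt3 was at -1.86, Apba1 at -1.67, P2rx3 at -2.07, Retnlg at 11.24, Stfa2 at 9.21 and Serpinb2 at 6.70. Without control clone 2 they were at -4.23, -4.34, -4.15, 7.89, 7.18 and 11.88. Retnlg was at 11.18 without day 4 replicate 1 of control clone 7.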

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

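The test of the difference between the hairpins was fixed before the values were seen, and the splits of the samples were chosen after. A difference between the hairpins in their net change picked out 8 genes, each with a log2 value for shOgdh346 minus shOgdh2081. Wfdc17 (3.51), Tgm2 (2.73), Gpnmb (2.69) and Dab2 (2.21) were higher with shOgdh346, and Zbtb16 (-2.02), Angpt1 (-1.67), Pdgfrb (-1.35) and Cnn3 (-1.27) were lower. Among the 3 splits of the 4 Ogdh clones into pairs, fitted on the 4 Ogdh clones alone with their own filter, the real split had 10 genes called, against 15 in the fit of all 6 clones, and the highest other 1, and 3 splits are too few for a share under 0.05.

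Single libraries lay far from the other 3 of their group in 9 of 174 groups looked at. For independent libraries chance alone picks about 1 in 20, or 8.7. The libraries of a group come in pairs from the same clone, so this rate need not hold here. Day 0 replicate 1 of control clone 7 held 13.2 M (13232745) counts against 7.28 to 8.01 M in the others, with 18457 genes detected against 17053 to 17088. Day 0 replicate 1 of shOgdh346 clone 1 held 18.7 M (18718239) counts against 7.45 to 9.11 M.

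Of the named genes, Serpinb2 stood at 1.11 CPM in day 0 replicate 1 of control clone 2 against 0 to 0.126 in the other 3 libraries, and Retnlg at 0.106 CPM in day 4 replicate 1 of control clone 7 against 0. In day 0 replicate 1 of shOgdh2081 clone 3, Il1rn stood at 9.65 CPM against 3.50 to 4.34 and Stfa2l1 at 17.99 against 11.8 to 12.3. Raet1d stood at 0.101 CPM in day 4 replicate 2 of control clone 2 against 0.461 to 0.530, and Aldh1l2 at 1.19 CPM in day 4 replicate 1 of shOgdh2081 clone 5 against 2.49 to 2.63.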

How the results depend on the processing

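The tests on day 0 libraries of a single replicate number, the replicate block of the within-day comparisons and the counts of genes shared by the hairpins were chosen after the result was seen. Of the gene values compared, 1150 of 1288 kept their direction and their side of the threshold with 1 clone left out, 4945 of 5056 with 1 library left out, 246 of 256 by DESeq2, 254 of 256 with either other scaling and 174 of 248 without the clone block. In simulated data with the design of these clones 44.3% of 1.5-fold net changes were recovered, against 64.3% with 24 libraries and a clone block. The simulated libraries were drawn independently, so this gain was built in. It does not bear on the larger counts with 24 real libraries. Without the clone block 0% of 1.5-fold and 34.3% of 2-fold simulated changes were recovered. False calls were 0%, against 10.9% with the block. The net fall of Ogdh lay between -1.93 and -1.61 under every alternative. Without the clone block, which leaves the spread between clones in the error, the count of genes was 2732 for the net change, 2296 for shOgdh346, 1212 for shOgdh2081, 1061 for genes shared by the hairpins, 147 for the control's change and 0 for the difference between hairpins. Leaving out 1 clone gave 2084 (without control clone 7) to 5521 (without shOgdh346 clone 5) for the net change, with lows without control clone 7 of 2108 for shOgdh346, 1118 for shOgdh2081, 1001 for shared genes and 2905 for the day 4 comparison. The highest values with 1 sample left out were 5018, 4005, 3443 and 5543 for these, each without a single day 4 library. The difference between hairpins had 692 genes with 24 libraries and a clone block, 347 with a replicate block, 101 by DESeq2, 23 with upper-quartile scaling, 409 with no filter, 44 with day 0 replicate 1 alone, and 2 to 59 with 1 sample left out. The control's change had 2765 with 24 libraries and a clone block, 2170 with a replicate block, 1719 with no filter, 1978 with day 0 replicate 1 alone, 122 with replicate 2 alone, and 8 to 1476 with 1 sample left out. The day 0 comparison had 4 genes with 24 libraries, 8 with a replicate block, 2 by DESeq2, 1 with no filter and 0 to 3 with 1 sample left out. Leaving out a control clone leaves 1 clone in that group, and fits of 24 libraries count libraries of one clone as separate samples. For the other changes the cause was not tested.

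Lists near 0 turned direction in some fits, and the cause was not tested. The mitochondrial DNA list had adjusted p of 0.847 with day 0 replicate 1 alone and of 0.641 (without control clone 2) to 0.938 (without shOgdh2081 clone 3). The MHC class II list had 0.816 by fry, 0.904 with day 0 replicate 1 alone, and 0.536 (without shOgdh346 clone 5) to 0.952 (without control clone 7). The net change of mt-Nd6 was -0.0116 without control clone 2 and 0.38 without control clone 7. In each of 6 clones, replicate deviations at day 0 and 4 correlated at -0.03 to 0.07. This cannot tell if replicates pair, as clones shared day 0 deviations (r = 0.56 to 0.72) but far less those at day 4. With the unit changed to 24 libraries and a replicate block, 38 of 39 lists, all but the stromal one, had the same result.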

Other observations

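The tests in this part were all chosen after the results were seen. GO terms of RNA processing were among those with more falls than rises in the net change, with 0 genes of the spliceosomal complex and nuclear pore terms and 1 tRNA processing gene in the fixed lists. Of 139 tested genes of the spliceosomal complex 4 rose and 78 fell, with a median net log2 change of -0.34 (hypergeometric test over 2433 GO terms, adjusted p = 4.67e-15). By camera this term had adjusted p = 9.46e-09 with the preset correlation and 0.494 with an estimated correlation, and the nuclear pore and tRNA processing terms also had 0.494. Prpf19, a ubiquitin ligase of the spliceosome, fell by -0.89 ± 0.10, the splicing factor Srsf2 by -0.84 ± 0.09 and the U4/U6 snRNP component Ppih by -1.03 ± 0.12 (SE). Of 58 nuclear pore genes 2 rose and 37 fell (adjusted p = 3.56e-09), among them the scaffold genes Nup85 and Nup133 at -1.03 ± 0.09 and -1.07 ± 0.11 and the membrane nucleoporin Nup210 at -1.30 ± 0.12. Of 78 tRNA processing genes 0 rose and 42 fell (adjusted p = 1.98e-07), with Mettl1, which methylates tRNA, at -1.05 ± 0.13 and the pseudouridine synthase Trub1 at -1.07 ± 0.14.

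Cell adhesion was among the terms with more rises than falls. Of 238 cell adhesion genes 88 rose and 22 fell (hypergeometric adjusted p = 6.55e-08; camera adjusted p = 7.92e-05, or 0.494 with an estimated correlation), among them the secreted glycoprotein Olfm4 at 4.72 ± 0.20, the tetraspanin Cd9 at 4.10 ± 0.20 and the leukocyte integrin subunit Itgb2 at 1.73 ± 0.13 (SE). Of 56 integrin binding genes 29 rose and 4 fell (adjusted p = 9.40e-06, or 0.494 by camera with an estimated correlation), with the metalloproteinase inhibitor Timp2 at 4.58 ± 0.33 and Icam2 at -0.68 ± 0.09. In the hypergeometric test genes count as independent, and 229 terms passed for rises and 191 for falls. Camera called 554 of 2433 terms with the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.494).

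The neutrophil maturation genes rose in all 4 Ogdh clones. A few genes taking many of the counts are argued against, as the top 10 genes held 3.63% to 8.98% of counts, which shifts other genes between libraries by at most 0.0824 on the log2 scale, while the list's lowest median under 3 scalings was 3.16. Cells of another animal with Y-linked transcripts are argued against in the 6 day 4 libraries without such transcripts, where the Y-linked counts allow at most 0.196% of such cells while the list held at least 2.00% of counts. Maturation of the knockdown cells and a change in which cells survive stay open and may both apply, since neither was tested.

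The control's change from day 0 to day 4, with Fosb and Klf2 among the falls, went along with the replicate number of the day 0 libraries. With replicate 2 alone as the baseline 122 genes passed, and another state of the cells in the replicate 1 libraries fits that count. The 980 genes called with both replicates, which include these libraries, kept a median change of 0.42 in the direction called, against 0.61 with both. Of them 976 kept their direction. As the whole cause, a state of the replicate 1 libraries alone is argued against. The 1749 genes called in replicate 1 libraries of both days had a median change of 0.64 there, in the direction called. In replicate 2 libraries of both days their median change in that direction was 0.26, with a lower quartile of 0.13. Depth is argued against, since with all libraries thinned to 7.21 M counts 129 genes passed with day 0 replicate 2 alone and 1736 with replicate 1 alone. Across 9582 genes the control's change correlated at r = 0.62 with the day 0 difference of replicate 2 minus replicate 1, which shares day 0 libraries. For the changes with shOgdh346 and shOgdh2081 r was 0.12 and 0.14. How the replicates were handled at day 0 stays open and could account for part or all of the control's change. A state of both day 0 replicates that was stronger in replicate 1 would pass the test above.

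Y-linked transcripts (Ddx3y, Kdm5d and Uty among them) were present in 2 of 6 clones, control clone 2 with 1507 to 1872 counts per library and shOgdh2081 clone 5 with 1822 to 2395, and the other 4 clones had 0 to 3. Depth is argued against, as at least 1383 counts would be expected in each library without them. An exchange of control and Ogdh clones is argued against by the share of day 0 Ogdh left at day 4, which was 61.5 percentage points higher in the lowest control clone than in the highest Ogdh clone. Loss of the Y chromosome in some clones and clones from different animals could both give this pattern and stay open. Xist had at most 1 count in any library, which gives no sign of female cells, but no library with Xist served as a reference. Clones with and without these transcripts, which share no library, had net changes that correlated at r = 0.89 across 9582 genes.

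Other splits of the clones were refitted for each comparison, on the clones and days compared alone with their own filter, so that counts of the real split differ from those above (10 against 15 for the difference between hairpins, 3798 against 5502 at day 4). For the net change 1 of 15 splits had as many genes as the real split, fitted with a single day term for the 4 Ogdh clones (4996 genes; highest other 0), and at day 4 1 of 15 did (3798; highest other 11). For each hairpin against the control 1 of 3 did (5479 with shOgdh346 and 4302 with shOgdh2081; highest other 0 in both), as for the difference between hairpins. These are too few splits for a share under 0.05. At day 0 all 15 of 15 did, the real split having 0 genes, and the highest other, 236, set the clones with Y-linked transcripts apart. Between days within a hairpin 1 of 35 splits of the libraries did with shOgdh346 (7485; highest other 153) and with shOgdh2081 (6504; highest other 259). In the control 2 of 35 did (1071), the other being the split into clone 2 and clone 7 with 2026. These splits within a hairpin take libraries of one clone as separate samples and use no clone block.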
